A study of Homo sapiens with 12 samples.

How the data were processed

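The samples were 12 arrays of RNA from MCF7 cells, 3 for each of 4 conditions kept for 24 hours, and the group of each array was taken from its title and growth condition label. The authors' deposited values are log2 expression values per probe set on Affymetrix human gene expression arrays. Per the submitters' processing notes they were made with Affymetrix Expression Console and RMA, which corrects background, quantile-normalises the arrays and summarises the probes of each set; versions are not given in the sources used here. Such normalisation gives the arrays nearly the same distribution (array medians ran from 6.35 to 6.41), so a change in total mRNA per cell would not appear. The log2 scale was checked from the range of values, from 2.61 to 14.2. Per the labels' protocols, total RNA was extracted with a kit for small and large RNA and labelled with biotin. Scanner files, detection calls and probe positions were not used here, so no coordinates are given.

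Genes were named through the platform annotation table supplied with the series. Of 22277 probe sets, 19070 have 1 gene, 1043 have several and were not used, and 2164 are not listed there. Leaving out the 62 Affymetrix control probe sets left 19064 with 1 gene. Symbols were updated by Entrez identifier through a gene table of the GRCh38.p14 assembly, which matched 11954 of the 11963 genes and was used for names only. For each gene the probe set with the highest mean over the 12 arrays was used, and no filter was placed on low values. Where the text names a gene in a contrast in which another called probe set of it went the other way, it says so. Among called genes with another called probe set, opposite signs occurred in 151 of 1030 (lactic acidosis), 126 of 1918 (hypoxia) and 231 of 1479 (combined, each against control), 222 of 1928 (combined against hypoxia), 289 of 1412 (combined against lactic acidosis) and 239 of 1776 genes (interaction).

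Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group means over all 12 arrays, 8 residual and 4.59 prior degrees of freedom, no covariate), with Benjamini-Hochberg adjustment over the genes of each contrast and a threshold of 0.05. The 6 contrasts were each treatment against control, the combined condition against hypoxia and against lactic acidosis, and the interaction, that is (combined minus hypoxia) minus (lactic acidosis minus control). With a median SE of 0.0656 per difference and 0.0927 for the interaction, small changes pass, so the number changed at least 2-fold is given beside each count. The 3 arrays of each group did not overlap for 45.6% (lactic acidosis), 61.3% (hypoxia) and 58.3% (combined) of genes against control, where chance gives 10%.

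The design, the alternatives, 27 gene lists (775 members, of which 669 were measured) and the rule for naming genes were fixed before the data were examined. The lists are HIF targets in glycolysis and elsewhere, the amino acid response, aminoacyl-tRNA synthetases, chaperones of the endoplasmic reticulum, DNA replication, mitosis, cholesterol synthesis, fatty acid synthesis, oxidative phosphorylation, the tricarboxylic acid cycle, estrogen response, p53 targets, the oxidative stress response, acid and lactate transport, lysosome and autophagy, ribosome biogenesis, cytosolic ribosomal proteins, NF-kB and inflammatory genes, interferon-stimulated genes, heat shock proteins, canonical histones, immediate early genes, and markers of luminal, stromal, leucocyte and basal cells. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 27 lists of a contrast, and again with an estimated correlation. With the latter, 9 of 12 called lists held in lactic acidosis, 5 of 12 in hypoxia and 3 of 11 in the combined arrays against control, 5 of 13 against hypoxia, 3 of 12 against lactic acidosis and 4 of 14 in the interaction. The rule named the 8 largest rises and 8 largest falls per contrast among called genes whose arrays do not overlap, up to 4 called members per list, and 27 fixed genes, of which 24 were measured and 3 were not analysed here.

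The scripts were tested on simulated data before use, with 50 genes of each size changed in 11963. A change of 1 log2 unit was recovered in 100% of cases in every contrast, and one of 0.25 in 50% (lactic acidosis), 36% (hypoxia) and 58% (combined, each against control), 42% (combined against hypoxia), 46% (combined against lactic acidosis) and 14% (interaction). Only 200 genes were changed in each simulation, far fewer than passed in the real data. The Benjamini-Hochberg adjustment is stricter where few genes change, so these shares understate the recovery of small changes in the real data. Alternatives were a replicate block, only the arrays compared, the mean of a gene's probe sets, every probe set, no probe sets ending in _x_at, no dim genes, median centring, renewed quantile normalisation, robust trended moderation, array weights and leaving out each array. Scaling on the poly-A controls was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.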

Results

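MCF7, an estrogen receptor-positive human breast cancer cell line, was kept for 24 hours in 4 conditions, and RNA from each was hybridised to 3 Affymetrix human gene expression arrays. Control cells stood in ambient air at neutral pH without lactate. Lactic acidosis meant 10 mM lactate at pH 6.7 in ambient air, and hypoxia meant 1% oxygen at neutral pH. The combined condition joined 1% oxygen with 10 mM lactate at pH 6.7, so that the series could show how the responses to acid and to low oxygen interact. Each of the 12 arrays gave a log2 value per probe set, from which 11963 genes were tested. Arrays of the same group correlated at 0.997 to 0.9986 across probe sets, and the hypoxia and combined arrays, the least alike, at 0.9712 to 0.9729. The number of arrays limits the precision. The labels do not say whether arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Differences between groups are given on the log2 scale ± SE from limma (3 arrays per group) or as folds, and the genes named for the largest changes are those whose arrays do not overlap between the groups compared.

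Bacterial poly-A control transcripts, which the standard Affymetrix protocol adds to the RNA before labelling, differed between the groups. Their mean log2 value over 24 probe sets was 7.72 ± 0.107 (SD, n = 3) in control, 7.81 ± 0.093 in lactic acidosis, 8.08 ± 0.119 in hypoxia and 8.58 ± 0.12 in the combined arrays. The combined arrays thus stood 0.86 ± 0.09 above control (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). Hybridisation controls, which are added after labelling, stood 0.14 higher (exact permutation p = 0.1). The 3' minus 5' difference of the *ACTB* control probe sets, a sign of RNA quality, was 1.12 ± 0.106 (SD, n = 3) in control, 1.24 ± 0.116 in lactic acidosis, 0.45 ± 0.086 in hypoxia and 1.07 ± 0.07 in the combined arrays. That of *GAPDH* differed less, at 0.211 ± 0.015, 0.22 ± 0.054, 0.091 ± 0.058 and 0.242 ± 0.021 in the same order. When each array was scaled on its poly-A controls, a step chosen after seeing the data, the median difference of all genes moved from 0.05 to -0.81 in combined against control, from 0.01 to -0.35 in hypoxia against control, and from 0.03 to -0.07 in lactic acidosis against control. All changes are therefore stated relative to the average of the arrays, and called gene lists whose median changed sign after spike-in scaling are named as such.

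**Figure D1:**
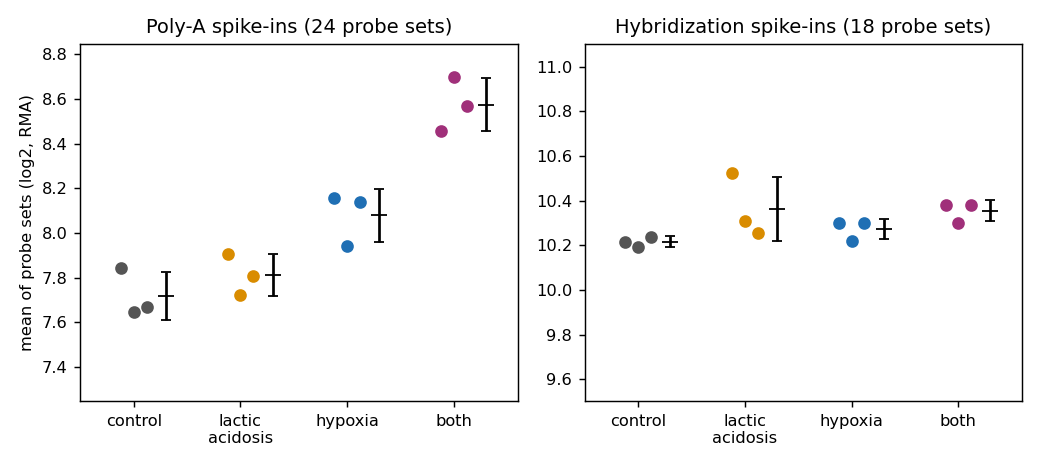
Mean log2 value of the poly-A control probe sets (left, 24 probe sets) and the hybridisation control probe sets (right, 18 probe sets) on each array, by group. Points are arrays and bars the group mean with its SD (n = 3), with the poly-A controls at 7.72 in control and 8.58 in the combined arrays and the hybridisation controls at 10.21 and 10.35.

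Lactic acidosis in ambient air was compared with control to show what lactate and acid alone did. *MAFF*, a small Maf transcription factor, was 6.55-fold higher (2.71 ± 0.075, adjusted p = 4.77e-10), with 0.48 on the other probe set of the gene. *GDF15*, a stress-induced cytokine, was 3.88-fold higher (1.96 ± 0.062, but 0.18 on a dimmer probe set), and *TXNIP*, which binds thioredoxin and restrains glucose uptake, was 3.85-fold higher (1.95 ± 0.059). *TGFBI*, *ALDH1A3*, *N4BP2L1*, *NDRG1* and *SPAG4* were 4.61-, 3.89-, 3.73-, 3.31- and 3.28-fold higher, though *N4BP2L1* rose by 1.90 on the probe set used, by 0.60 on 2 about as bright and by -0.02 to 0.08 on the others. *GJA1*, a connexin of gap junctions, fell most, by 1.77 ± 0.126 (3.41-fold), followed by *PCDH9*, *GDAP1*, *SLC39A8*, *TP53I3*, *PDZK1*, *CXCR4* and *DNAJB6*, which were 2.73- to 2.36-fold lower. Other probe sets showed 0.00 for *PCDH9*, -1.12 to 0.03 for *SLC39A8* and -0.79 and -0.61 for *CXCR4*. In all, 4299 genes changed, 2170 higher and 2129 lower, and 57 of the higher and 26 of the lower genes changed at least 2-fold. After spike-in scaling 2393 genes passed, 28.4% of them higher, against 50.5% without it.

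Targets of the hypoxia-inducible factors (HIF) rose in lactic acidosis although oxygen was at the ambient level. Of 37 measured HIF targets outside glycolysis, 26 rose and 2 fell (median 0.50, camera adjusted p = 1.62e-10), and adjusted over the list alone 26 rose and 4 fell. *BNIP3*, a mitophagy receptor, was 2.01-fold higher, *LOXL2*, a lysyl oxidase, 2.06-fold, and the vasodilator peptide gene *ADM* 1.96-fold, with 0.07 and 0.00 on the dimmer probe sets of *LOXL2*. *VEGFA* rose by 0.74 ± 0.074 (0.30 to 0.52 on its other probe sets), and the message of *HIF1A* itself by 0.24 ± 0.050. Of 23 HIF targets in glycolysis and glucose storage 13 rose and 2 fell, also adjusted over the list alone (median 0.18, adjusted p = 0.00424). These included *PFKFB3* (2.31-fold) and *PGM1* (1.95-fold), whereas the glucose transporter gene *SLC2A1* was 1.16-fold lower (not past the threshold with the mean of its probe sets, adjusted p = 0.0519) and *EGLN3* did not pass the test (-0.30 ± 0.122, adjusted p = 0.0733). Immediate early genes, the transcription factors and regulators that respond first to a stimulus, rose in 18 of 23 cases with none lower, also adjusted over the list alone (median 0.45, adjusted p = 9.35e-08). *JUN* was 2.22-fold, *EGR1* 2.15-fold and *KLF10* 1.86-fold higher. Among 21 NF-kB and inflammatory genes 12 rose and 1 fell under both adjustments (median 0.26, adjusted p = 0.00072), with *TNFAIP3* 2.01-fold and *CXCL8* 1.90-fold higher (0.23 on its dim probe set).

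Genes for growth and lipid synthesis fell in lactic acidosis. Of 37 genes of DNA replication and S phase 29 fell and 1 rose under both adjustments (median -0.25, adjusted p = 2.11e-10), led by *MCM10* (1.75-fold lower). Of 29 ribosome biogenesis genes 21 fell and 1 rose (23 and 1 adjusted over the list alone; median -0.33, adjusted p = 1.05e-09), with *UTP20* 1.88-fold lower. The member that rose was *MYC* (1.66-fold), a transcription factor that also stands among the immediate early genes. Cholesterol synthesis (11 lower and 1 higher of 18, median -0.23, adjusted p = 3.2e-05) and fatty acid synthesis (8 lower of 11, median -0.24, adjusted p = 0.000242) fell under both adjustments, and *ACACB*, an acetyl-CoA carboxylase, was 2.19-fold lower (-0.94 to -0.13 on its other probe sets). Canonical histone genes fell in 16 of 25 cases under both adjustments (median -0.35, adjusted p = 1.91e-07). Heat shock proteins (10 lower and 2 higher of 16, median -0.24, adjusted p = 0.00551), aminoacyl-tRNA synthetases (8 lower and 1 higher of 16, median -0.11, adjusted p = 0.00719) and mitosis genes (13 lower and 6 higher of 42, 16 and 6 adjusted over the list alone, median -0.09, adjusted p = 0.0229) also passed with the preset correlation of camera. The adjusted p of these 3 lists was 0.0908, 0.298 and 0.501 with an estimated correlation, which left 9 of the 12 called lists. The mitosis call was also lost without lactic acidosis replicate 3 (adjusted p = 0.155), without the dimmest genes (0.0985) and after renewed quantile normalisation (0.0948). The medians of all 12 lists kept their sign after spike-in scaling. Genes of the amino acid response, the transcriptional program of ATF4, did not shift as a list (14 higher, 7 lower of 35, 15 and 7 adjusted over the list alone, adjusted p = 0.12), and *TRIB3* (0.01 ± 0.043) and *DDIT3* (0.05 ± 0.079) did not pass the test. Leucocyte, stromal and basal epithelial markers, which would point to other cells, were not called in any contrast, and their medians in lactic acidosis were -0.001, 0.06 and 0.01.

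Hypoxia at neutral pH was compared with control to show the response to low oxygen alone. Among the comparisons with control it gave the largest single rise. *ADM* rose 67-fold (6.07 ± 0.091, adjusted p = 4.62e-14), *TMEM45A* 65.7-fold and *NDRG1* 42.8-fold. *TMEM45A* lay at 4.488 to 4.718 in control, below the lower quartile of each of those arrays (4.72 to 4.767), so its fold rests on dim control values. The lysyl oxidase genes *LOXL2* and *LOX* rose 33.8- and 22.8-fold, though dimmer probe sets of *LOXL2* showed 0.85 and -0.05, and one of *LOX* 1.04. *CYP1A1*, a cytochrome P450 that oxidises aromatic compounds, rose 24.5-fold, *PPFIA4* 22.1-fold and the aldolase gene *ALDOC* 16.5-fold. The kinase gene *SGK1* fell by 3.08 ± 0.130 (8.46-fold). *CTPS1*, which makes cytidine triphosphate, *MCM10*, which loads the replication machinery, and *ODC1*, the first enzyme of polyamine synthesis, were at -3.00 ± 0.087, -2.86 ± 0.072 and -2.79 ± 0.046, followed by *CXCL12*, *GPATCH2*, *PDZK1* and *NAA15*, which were 5.65- to 4.70-fold lower. In all, 6436 genes changed, 3050 higher and 3386 lower, of which 439 and 429 changed at least 2-fold. After spike-in scaling 8952 genes passed, 11.2% of them higher, against 47.4% without it.

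All 37 HIF targets outside glycolysis rose in hypoxia (median 2.51, 5.70-fold, adjusted p = 1.19e-27), and 22 of the 23 in glycolysis (median 1.12, 2.18-fold, adjusted p = 1.25e-15), with the same counts adjusted over the list alone. *BNIP3* was 6.86-fold, *EGLN3*, an oxygen-sensing prolyl hydroxylase, 8.16-fold, *VEGFA* 6.95-fold, *PDK1* 4.92-fold, *SLC2A1* 3.48-fold and *LDHA* 1.69-fold higher. *HIF1A* message was 1.77-fold lower, and that of *EPAS1*, which encodes the HIF-2 alpha subunit, 3.22-fold higher (0.39 on its dim probe set). The amino acid response rose in 23 and fell in 4 of 35 genes (23 and 5 adjusted over the list alone; median 0.58, adjusted p = 3.69e-06), with *DDIT4* 9.69-fold, *GDF15* 9.26-fold (0.33 on the dimmer probe set), *TRIB3* 2.86-fold and *ATF4* itself 1.71-fold higher. *DDIT4* and *NDRG1* stand in this list and in that of HIF targets.

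DNA replication genes fell in 36 of 37 cases under both adjustments (median -1.03, 2.04-fold, adjusted p = 1.04e-17). *CCNE2*, the helicase subunit *MCM6* and the sliding clamp *PCNA* were 3.72-, 3.67- and 3.58-fold lower. The mitosis list did not pass (7 higher, 18 lower of 42, adjusted p = 0.119). Ribosome biogenesis fell in 25 and rose in 2 of 29 genes (26 fell adjusted over the list alone; median -0.66, adjusted p = 2.33e-08), with *RRS1* 3.27-fold lower. The tricarboxylic acid cycle (14 lower, 3 higher of 18, median -0.50, adjusted p = 0.00244) and oxidative phosphorylation (34 lower, 4 higher of 58, 36 and 4 adjusted over the list alone, median -0.24, adjusted p = 2.3e-05) fell. *IDH3A* was 3.30-fold and *CYCS*, cytochrome c, 2.06-fold lower. Heat shock proteins fell in 11 and rose in 5 of 16 cases (median -0.61, adjusted p = 0.00747), led by *HSPH1* at 4.48-fold lower. The adjusted p of these 3 lists was 0.134, 0.277 and 0.134 with an estimated correlation. Endoplasmic reticulum chaperones were 13 lower and 6 higher of 25 without passing as a list (adjusted p = 0.119), with *HYOU1* 3.25-fold and *HSPA5* 1.33-fold lower. The estrogen receptor gene *ESR1* was 2.01-fold (-0.30 to 0.05 on its dimmer probe sets) and its target *PGR* 2.17-fold lower, while the estrogen response list did not pass (10 higher, 18 lower of 33, adjusted p = 0.148).

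Immediate early genes (16 higher, 1 lower of 23, median 0.36, adjusted p = 2.3e-05), interferon-stimulated genes (14 and 2 of 25, or 15 and 2 adjusted over the list alone, median 0.27, adjusted p = 0.00277), lysosome and autophagy genes (18 and 7 of 32, median 0.24, adjusted p = 0.00969) and canonical histone genes (11 and 4 of 25, median 0.19, adjusted p = 0.0249) rose relative to the array average, but not after spike-in scaling. Their medians were -0.002, -0.09, -0.12 and -0.17 after spike-in scaling, and their adjusted p was 0.0948, 0.36, 0.136 and 0.328 with an estimated correlation. The histone call was also lost without probe sets ending in _x_at (0.0735). For all called lists of this contrast the counts adjusted over the list alone were the same unless given. *FOS* was 7.21-fold, *ATF3* 5.13-fold and *ISG20* 3.24-fold higher, and *EGR3* 3.42-fold lower. *HMOX1*, heme oxygenase, rose by 3.81 ± 0.097, while the oxidative stress list around it did not pass (14 higher, 8 lower of 23, adjusted p = 0.154). Also short of the threshold were p53 targets (10 higher, 5 lower of 23, adjusted p = 0.0573), acid and lactate transport (5 and 8 of 20, adjusted p = 0.412), cholesterol synthesis (9 and 6 of 18, adjusted p = 0.583) and cytosolic ribosomal proteins (7 and 0 of 39, 2 and 0 adjusted over the list alone, adjusted p = 0.429). The growth factor receptor gene *EGFR*, listed among basal epithelial markers, was 5.36-fold higher (2.42 and 2.54 on its 2 brightest probe sets, but -0.06 to 0.17 on the others), and the luminal list that MCF7 cells should express had a median of -0.01 (5 higher, 4 lower of 14, or 5 each adjusted over the list alone).

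Overlap of the 2 single responses was counted because both used the same control arrays. Genes higher in both lactic acidosis and hypoxia numbered 1455 and genes lower in both 1637, while 379 went opposite ways. Independent lists of these sizes would give 553, 603 and 1157. Unchanged groups simulated against the same controls gave 0 in each class in 50 simulations. With no true change hardly any gene is called, so this 0 does not measure what shared controls add to the overlap. Across genes, the 2 effects correlated at 0.594, against 0.503 simulated from shared controls alone, and their covariance was 0.088 against 0.00272. The simulated correlation follows by construction when unchanged groups share controls of equal size. It is therefore no baseline for groups in which genes changed. The covariance from shared controls alone was small beside the observed one. *TXNIP* (3.85- and 5.36-fold), *NDRG1* (3.31- and 42.8-fold) and *GDF15* (3.88- and 9.26-fold) were among the genes higher in both. Genes are not independent replicates, and 3 control arrays cannot be split between the comparisons. Their part was simulated only for the correlation and covariance of unchanged groups, and their part in the overlap counts was not measured.

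The combined condition was compared with control to show what acid and low oxygen did together. *MAFF* was 65.6-fold higher (6.04 ± 0.075, adjusted p = 2.1e-14, with 3.07 for its other probe set), *ADM* 28.3-fold, and *CCN2* and *CCN1*, secreted matricellular proteins, 20.4- and 11.2-fold. *CCN2* lay at 3.67 to 4.14 in control, below the lower quartile of those arrays (4.72 to 4.77), so its fold rests on dim control values. *ATF3* was 19.8-fold, *CYP1A1* 15.8-fold, *DDIT4* 10.5-fold and *GADD45B* 9.64-fold higher (1.57 to 3.05 on its other probe sets). *SGK1* fell by 4.08 ± 0.130 (16.9-fold), *PIK3R1*, a regulatory subunit of phosphoinositide kinase, was at -3.17 ± 0.072 (with -1.26 and -1.35 for its other probe sets) and *FLRT3* at -2.82 ± 0.111. *ZC3HAV1*, an antiviral RNA-binding protein, was 8.89-fold lower on the probe set used but 0.39 higher on the other. *UNC119B*, *KIAA0232*, the mRNA 3' end processing factor *PCF11* and the nuclear receptor corepressor *NRIP1* were 6.37-, 6.23-, 6.06- and 5.67-fold lower, with -1.45 for the other probe set of *NRIP1*. In all, 5674 genes changed, 2931 higher and 2743 lower, with 128 and 255 at least 2-fold. After spike-in scaling 11815 genes passed, 0.956% of them higher, against 51.7% without it.

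Among lists, immediate early genes rose in 18 and fell in 2 of 23 cases (median 1.27, 2.41-fold, adjusted p = 4.23e-10), and canonical histone genes in 21 of 25 with none lower (23 adjusted over the list alone; median 1.10, 2.14-fold, adjusted p = 5.02e-13). These medians stayed above control after spike-in scaling, at 0.41 and 0.24. The RNA decay factor *ZFP36* was 8.54-fold higher, and *H2AC8* and *H1-2* 6.40- and 4.14-fold. NF-kB and inflammatory genes rose in 14 of 21 with none lower under both adjustments (median 0.39, adjusted p = 2.45e-07, -0.47 after spike-in scaling), with *TNFAIP3* 8.41-fold, *IRF1* 7.41-fold and *TNF* 3.71-fold higher. Interferon-stimulated genes rose in 22 of 25 and fell in 1 (median 0.45, adjusted p = 4.79e-08 but 0.189 with an estimated correlation, and -0.41 after spike-in scaling). Of HIF targets outside glycolysis 24 of 37 rose and 6 fell (25 and 6 adjusted over the list alone; median 0.39, adjusted p = 3.24e-06 but 0.0519 with an estimated correlation, and -0.46 after spike-in scaling), and in glycolysis 11 of 23 rose and 2 fell (median 0.12, adjusted p = 0.0101 but 0.0876 with an estimated correlation, and -0.74 after spike-in scaling). *ADM*, *DDIT4*, *BHLHE40* (8.79-fold) and *HILPDA* (7.63-fold) were higher, whereas *EGLN3* was 1.51-fold and *EPAS1* 1.47-fold lower (0.19 on its dim probe set) and *LDHA* lay at 0.01 ± 0.042. *VEGFA* rose by 0.56 and 0.73 on its brighter probe sets, but by 2.61 on each of the others.

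*HSPA5*, the main chaperone of the endoplasmic reticulum, was 2.06-fold higher, *DNAJB9* 3.38-fold and *HERPUD1* 3.09-fold, while *SPCS3* was 1.69-fold lower on the probe set used but at 0.16 on the other. The list as a whole did not pass (10 higher, 5 lower of 25, 11 and 5 adjusted over the list alone, adjusted p = 0.0899). The transcription factor *DDIT3*, also called CHOP, was 4.28-fold higher, but *TRIB3* was at -0.08 ± 0.043, and the amino acid response list missed the threshold (18 higher, 8 lower of 35, 18 and 9 adjusted over the list alone, adjusted p = 0.0506). DNA replication genes were 7 higher and 14 lower of 37 (median -0.03, adjusted p = 0.235). The smaller called shifts were oxidative phosphorylation (25 higher, 3 lower of 58, median 0.10), cytosolic ribosomal proteins (15 and 0 of 39, 0.09), lysosome and autophagy (17 and 3 of 32, 0.19), ribosome biogenesis (3 and 13 of 29, -0.12) and mitosis (6 and 16 of 42, -0.11). With an estimated correlation their adjusted p was 0.513, 0.513, 0.189, 0.189 and 0.521. Adjusted over the list alone 7 mitosis genes rose, and for the other called lists the counts were the same unless given. The mitosis call was lost without control replicate 1 or 3 (adjusted p = 0.0586 and 0.0536) and without combined replicate 1 or 2 (0.0669 and 0.0553). It was also lost without the dimmest genes (0.236), after renewed quantile normalisation (0.0861), without probe sets ending in _x_at (0.0848), after median centring (0.0647) and with robust trended moderation (0.0535). The ribosome biogenesis call was lost without the dimmest genes (0.148), after quantile normalisation (0.0853) and with the mean of probe sets (0.0533), and the calls of ribosomal proteins and oxidative phosphorylation after quantile normalisation (0.0732 and 0.0696). The medians that were above control all lay below it after spike-in scaling, at -0.76, -0.77 and -0.67.

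**Figure D2:**
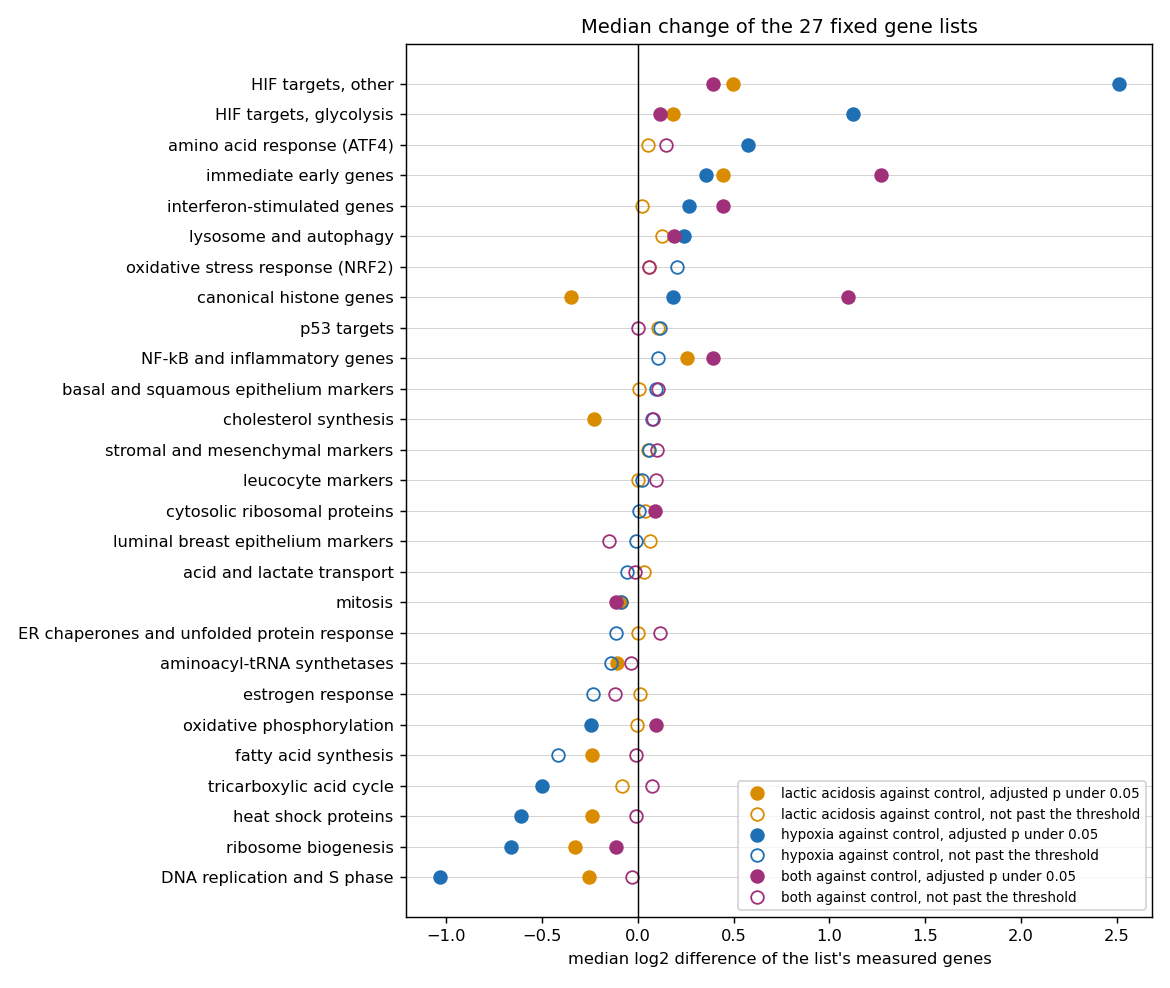
Median log2 difference from control of each of the 27 gene lists fixed before the data were examined, in lactic acidosis, hypoxia and both together. Filled points passed camera at an adjusted p under 0.05, and HIF targets outside glycolysis stood at 2.51 in hypoxia and 0.39 in the combined condition, which became 2.15 and -0.46 after spike-in scaling.

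The question in the series title, how the responses to lactic acidosis and hypoxia interact, was addressed by the departure of the combined condition from the sum of both single effects. Hypoxia-raised genes departed downward and hypoxia-lowered genes upward. *NDRG1* averaged 7.37 ± 0.116 (SD, n = 3) in control, 9.09 ± 0.108 in lactic acidosis, 12.78 ± 0.046 in hypoxia and 8.56 ± 0.209 in the combined arrays, an interaction of -5.95 ± 0.133 (adjusted p = 5.24e-12). *TMEM45A* averaged 4.61 in control, 5.08 in lactic acidosis, 10.65 in hypoxia and 4.66 in the combined arrays (interaction -6.45 ± 0.157). *ADM* differed in degree, at 5.15 in control, 6.12 in lactic acidosis, 11.21 in hypoxia and 9.97 in the combined arrays (interaction -2.21 ± 0.128). *MCM10*, in contrast, fell from 9.69 to 8.88 in lactic acidosis and to 6.83 in hypoxia, yet stood at 9.24 in the combined arrays (interaction 3.21 ± 0.102). In all, 6230 genes passed the interaction test, 3113 with a positive and 3117 with a negative value, and 703 and 885 of them reached 2-fold. After spike-in scaling 7636 passed, 15.1% of them positive, against 50% without it.

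**Figure D3:**
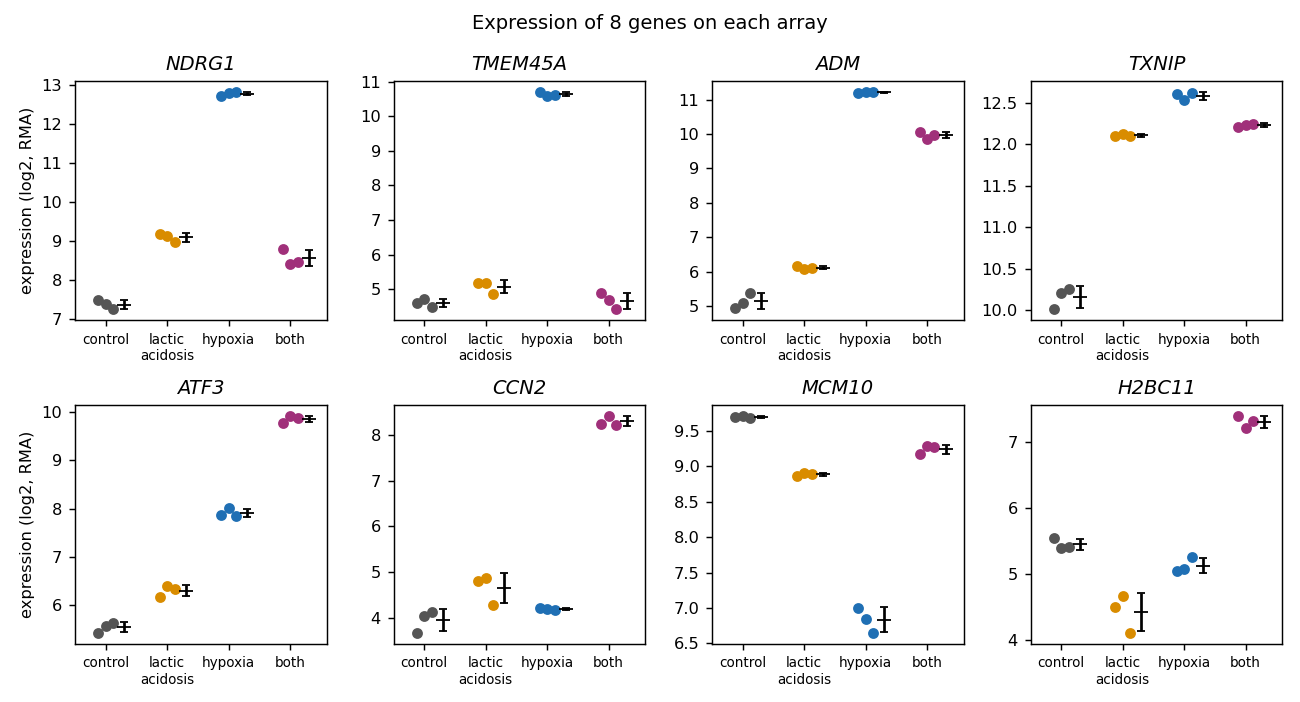
Log2 expression of 8 genes on each of the 12 arrays, by group. Points are arrays and bars the group mean with its SD (n = 3), and *NDRG1* and *TMEM45A* were highest in the hypoxia arrays (12.78 and 10.65), while *ATF3*, *CCN2* and *H2BC11* were highest in the combined arrays (9.86, 8.30 and 7.30).

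HIF targets showed this departure as groups. Outside glycolysis 34 of 37 had a negative interaction and 2 a positive one (median -2.25, adjusted p = 3.09e-18), and in glycolysis 22 of 23 had a negative one (median -1.11, adjusted p = 7.38e-13). *LOXL2* (-6.19 ± 0.118), *SPAG4* (-5.20 ± 0.078), *LOX* (-5.00 ± 0.160), *BNIP3* (-3.38 ± 0.108), *EGLN3* (-3.32 ± 0.172) and *VEGFA* (-2.98 ± 0.104) stood among them. The dimmer probe sets of *LOXL2* had interactions of -0.80 and 0.27, and one of *LOX* -1.09. Probe sets of *VEGFA* ranged from -2.98 to 0.32, so its interaction depends on the probe set. Genes outside these lists included *PPFIA4* (-5.76 ± 0.156), *TGFBI* (-5.02 ± 0.106) and *SAMD4A* (-4.95 ± 0.199, but -0.98 to -0.19 on its dimmer probe sets). *TXNIP* stood at 10.16 in control, 12.11 in lactic acidosis, 12.59 in hypoxia and 12.23 in the combined arrays (interaction -2.30 ± 0.084). It thus stayed near its level in each single condition. The sum of both single effects would lie above 14.199, the highest value on any array. The range of the arrays alone therefore made a negative interaction of *TXNIP* likely.

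Positive interactions prevailed among genes of DNA replication (36 of 37, median 1.34, adjusted p = 8.66e-17) and ribosome biogenesis (24 positive, 1 negative of 29, median 0.91, adjusted p = 4.49e-08), both of which stayed above 0 after spike-in scaling at 0.93 and 0.51. *CTPS1* (3.20 ± 0.123), the spermidine synthase gene *SRM* (2.74 ± 0.078), *PDZK1* (3.24 ± 0.131), *GPATCH2* (2.78 ± 0.087) and *MAOB* (2.87 ± 0.127) moved likewise. Canonical histone genes (23 positive, 2 negative of 25, median 1.37, adjusted p = 9.21e-08 but 0.0636 with an estimated correlation) differed in their source, since they fell in lactic acidosis and rose in the combined arrays. *H2BC11* averaged 5.44, 4.42, 5.12 and 7.30 in control, lactic acidosis, hypoxia and both. Heat shock proteins (10 and 4 of 16, median 0.72), fatty acid synthesis (7 and 3 of 11, 0.74) and the tricarboxylic acid cycle (14 and 2 of 18, 0.63) passed, with adjusted p of 0.105, 0.15 and 0.0951 with an estimated correlation. Oxidative phosphorylation (39 and 3 of 58, 0.40), chaperones of the endoplasmic reticulum (15 and 2 of 25, 0.33), cholesterol synthesis (12 and 3 of 18, 0.36) and aminoacyl-tRNA synthetases (9 and 3 of 16, 0.33) passed too. Their adjusted p was 0.176, 0.0951, 0.0951 and 0.327 with an estimated correlation, and their medians were -0.01, -0.07, -0.04 and -0.07 after spike-in scaling. Negative lists were the amino acid response (9 positive, 20 negative of 35, median -0.29, 0.129 as its adjusted p with an estimated correlation) and p53 targets (6 and 13 of 23, -0.57, 0.371 as its adjusted p with an estimated correlation). The p53 call was lost without control replicate 2 (adjusted p = 0.0508), lactic acidosis replicate 2 or 3 (0.0713 and 0.0504) or hypoxia replicate 3 (0.064). It was also lost without probe sets ending in _x_at (0.0961), with the mean of probe sets (0.09), without the dimmest genes (0.0826), with the replicate block (0.0707) and with array weights (0.0532). The calls of the aminoacyl-tRNA and fatty acid lists were lost without the dimmest genes (0.0658 and 0.0749), and the former after quantile normalisation (0.062). Counts adjusted over the list alone were the same for all 14 called lists except ribosome biogenesis (24 and 2) and aminoacyl-tRNA synthetases (10 and 3).

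HIF targets were lower in the combined than in the hypoxia arrays. The combined arrays were set against the hypoxia arrays, a contrast that shares no array with lactic acidosis against control. Outside glycolysis 33 of 37 fell and 2 rose (median -1.90, 3.72-fold lower, adjusted p = 1.64e-17), and in glycolysis 22 of 23 fell (median -1.20, 2.30-fold lower, adjusted p = 2.54e-14), under both adjustments. *TMEM45A* was 63.2-fold, *LOXL2* 35.4-fold, *PPFIA4* 23.1-fold, *LOX* 22.5-fold, *NDRG1* 18.7-fold and *EGLN3* 12.3-fold lower, whereas *ADM* was 2.37-fold lower. *TMEM45A* lay at 4.423 to 4.889 in the combined arrays, near their lower quartile (4.799 to 4.829), so its fold rests on dim values. *LRP4*, *FLRT3* and *SAMD4A* were 15.6-, 14.4- and 12.9-fold lower, with -0.72 to -0.03 on the dimmer probe sets of *SAMD4A* and -1.13 on one of *LOX*. The messages of the HIF subunits moved apart, with *HIF1A* 2.02-fold higher and *EPAS1* 4.73-fold lower (-2.24, but -0.19 on its dim probe set). *LOXL2* fell by 5.14 on the probe set used, against -0.74 and 0.28 on its dimmer probe sets. In all, 6676 genes changed, 3589 higher and 3087 lower, with 394 and 613 at least 2-fold. After spike-in scaling 9981 passed, 7.67% of them higher, against 53.8% without it.

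DNA replication genes were higher in the combined than in the hypoxia arrays (36 of 37, median 1.00, 2.00-fold, adjusted p = 4.85e-15), as were ribosome biogenesis genes (22 higher, 3 lower of 29, median 0.59, adjusted p = 3.12e-05). *MCM10* was 5.30-fold, *CTPS1* 6.11-fold and *PCNA* 3.52-fold higher. *CCN2* (17.2-fold), *CCN1* (7.31-fold), *ZFP36* (6.58-fold), *IRF1* (5.53-fold), *RND1* (5.23-fold) and *AUNIP* (4.95-fold) rose too. *CCN2* lay at 4.176 to 4.207 in hypoxia, below the lower quartile of those arrays (4.77 to 4.8), so its fold rests on dim values. NF-kB and inflammatory genes passed (11 higher of 21, none lower, median 0.21, adjusted p = 0.00138, -0.29 after spike-in scaling). Histones (22 and 3 of 25, median 0.82), heat shock proteins (11 and 4 of 16, 0.64) and the tricarboxylic acid cycle (15 and 2 of 18, 0.50) were higher, with adjusted p of 0.106, 0.113 and 0.0972 with an estimated correlation. Oxidative phosphorylation (44 and 2 of 58, 0.36), chaperones of the endoplasmic reticulum (15 and 4 of 25, 0.42) and immediate early genes (14 and 5 of 23, 0.38) had adjusted p of 0.142, 0.113 and 0.25 with an estimated correlation and medians of -0.14, -0.08 and -0.12 after spike-in scaling. *HSPA5* was 2.74-fold and *HYOU1* 3.51-fold higher. The amino acid response was lower (8 higher, 20 lower of 35, median -0.27), and so were p53 targets (7 and 13 of 23, -0.41), with adjusted p of 0.142 and 0.443 with an estimated correlation. *SLC7A11*, the cystine transporter, was 5.59-fold (-2.97 and -0.42 on its other probe sets) and *TRIB3* 3.02-fold lower, but *ATF3* 3.86-fold and *DDIT3* 1.82-fold higher. The p53 call was lost without lactic acidosis replicate 1, 2 or 3 (adjusted p = 0.0519, 0.053 and 0.0503) and without hypoxia replicate 3 (0.064). It was also lost with the mean of probe sets (0.136, where the median was -0.138), without the dimmest genes (0.127), without probe sets ending in _x_at (0.0984) and with the replicate block (0.0623). The call of immediate early genes was lost without the dimmest genes (0.057). Adjusted over the list alone the counts of the called lists were the same, except 15 and 5 for immediate early genes and 45 and 2 for oxidative phosphorylation.

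HIF targets did not pass as a group in the combined against the lactic acidosis arrays. Of the 37 outside glycolysis 12 rose and 18 fell (12 and 21 adjusted over the list alone; median -0.19, mean 0.21, adjusted p = 0.671), so that median and mean differed in sign, and of the 23 in glycolysis 7 rose and 7 fell (median 0.06, adjusted p = 0.861). Exceptions were *ADM* (14.4-fold higher), *DDIT4* (6.17-fold), *HILPDA* (5.53-fold) and *BHLHE40* (4.38-fold). *CYP1A1* was 10.1-fold, *MAFF* 10.0-fold, *ATF3* 11.8-fold, *CCN2* 12.5-fold and *CCN1* 7.51-fold higher. *CCN2* lay at 4.278 to 4.864 in lactic acidosis, near the lower quartile of those arrays (4.75 to 4.816), so its fold rests on dim values. *SGK1*, *ZC3HAV1*, *KIAA0232*, *PIK3R1*, *NRIP1*, *TNS3*, *UNC119B* and *ADCY1* were 8.21- to 5.36-fold lower, but the other probe set of *ZC3HAV1* was 0.74 higher, and other probe sets of *PIK3R1*, *NRIP1* and *ADCY1* lay between -0.51 and 0.15. In all, 5389 genes changed, 2600 higher and 2789 lower, with 105 and 275 at least 2-fold. After spike-in scaling 11607 passed, 0.905% of them higher, against 48.2% without it. All 25 histone genes were higher under both adjustments (median 1.62, 3.07-fold, adjusted p = 7.64e-19, 0.86 after spike-in scaling), with *H2BC11* at 7.38-fold.

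Of the other 11 called lists all had a median above 0 relative to the array average and below 0 after spike-in scaling. NF-kB and inflammatory genes (10 higher of 21, median 0.15, adjusted p = 0.000314) and cholesterol synthesis (14 higher, 2 lower of 18, median 0.39, adjusted p = 9.07e-05) also passed with an estimated correlation. Interferon-stimulated genes (17 and 1 of 25, median 0.40), immediate early genes (17 and 5 of 23, 0.54) and DNA replication (23 and 3 of 37, 0.20) did not, at adjusted p of 0.187, 0.0975 and 0.244 with an estimated correlation. *IFI44L* was 3.98-fold, *TNFAIP3* 4.19-fold, *HSD17B7* 2.57-fold and *HSPA5* 1.95-fold higher. Chaperones of the endoplasmic reticulum (16 and 5 of 25), ribosome biogenesis (16 and 5 of 29), the tricarboxylic acid cycle (8 and 1 of 18), oxidative phosphorylation (28 and 2 of 58), fatty acid synthesis (6 and 0 of 11) and aminoacyl-tRNA synthetases (10 and 2 of 16) had medians of 0.26, 0.20, 0.14, 0.13, 0.14 and 0.18. Their adjusted p was 0.187, 0.187, 0.189, 0.401, 0.187 and 0.401 with an estimated correlation. The calls of the fatty acid and aminoacyl-tRNA lists were lost without lactic acidosis replicate 3 (adjusted p = 0.0541 and 0.0572) and without combined replicate 2 (0.0525 for both). After quantile normalisation they were lost too (0.0555 and 0.0918), as was that of oxidative phosphorylation (0.0555). Adjusted over the list alone the counts of the called lists were the same, except 18 and 1 for interferon-stimulated genes, 11 and 2 for aminoacyl-tRNA synthetases and 28 and 3 for oxidative phosphorylation.

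**Figure D4:**
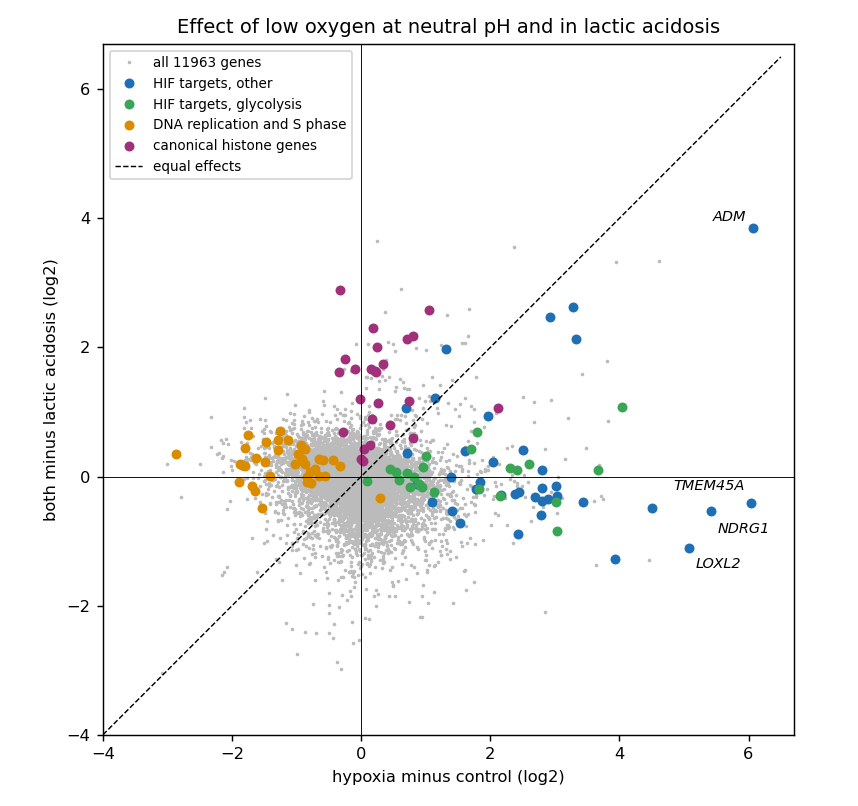
Log2 effect of low oxygen at neutral pH (x axis, hypoxia minus control) against its effect in lactic acidosis (y axis, combined minus lactic acidosis) for 11963 genes, with 4 gene lists coloured and a dashed line of equal effects. HIF targets outside glycolysis lie far to the right and on both sides of 0 on the y axis (medians 2.51 and -0.19), and histone genes lie above 0 on it (median 1.62, or 0.86 after spike-in scaling).

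Across all genes, the effect of lactic acidosis in low oxygen ran against its effect in ambient air (Pearson r = -0.336, Spearman rho = -0.318, slope -0.725 over 11963 genes), but not over the 6047 genes within 0.2 of control in hypoxia (r = 0.153). The effect of hypoxia in lactic acidosis was nearly unrelated to that at neutral pH (r = -0.068, rho = -0.141, slope -0.049). These are 2 relations across genes, which are not independent replicates, and no p is given. Of the 3050 genes higher in hypoxia, 2238 had a negative interaction and 87 a positive one, and of the 3386 lower ones 2522 had a positive and 217 a negative one. Of the 2170 genes higher in lactic acidosis 1548 had a negative and 131 a positive interaction, and of the 2129 lower ones 1615 had a positive and 171 a negative one. Simulated data with the same single effects and no interaction gave 0 such genes on average in each class in 50 simulations. With no true interaction hardly any gene passes that test, so this 0 was nearly fixed in advance. It does not measure how much the arrays shared by the single contrasts and the interaction add to the opposite signs. *NDRG1*, *BNIP3* and *TXNIP* were genes higher in both single conditions with a negative interaction, and *MCM10*, *CTPS1* and *PDZK1* were lower in both with a positive one. For *NDRG1* and *TXNIP* the sum of both single effects would lie above 14.199, the highest value on any array. Part of their negative interaction can therefore come from the range of the arrays.

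The median, mean and camera direction of a list differed in sign in no called list. Among lists that did not pass, they differed for estrogen response, acid and lactate transport, interferon-stimulated genes and leucocyte markers in lactic acidosis, and for luminal markers in hypoxia. In the combined arrays they differed for p53 targets, acid and lactate transport, heat shock proteins and luminal markers against control, and for stromal and basal markers against hypoxia. Against lactic acidosis they differed for HIF targets outside glycolysis, mitosis, estrogen response and p53 targets.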

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

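The tests of exchanged labels, ambient oxygen and scaling for HIF targets and of hybridisation for the spike-in controls were chosen only after the result was seen. The effect of lactic acidosis differed between ambient air and low oxygen for 6230 genes, by the interaction test. The residuals of a fit without interaction were regrouped at random over the 12 arrays, in 100 arrangements with the real one included. Of these 1 gave as many genes, the real one, and the highest other count was 0. The residuals carry the interaction itself, which widens the spread and lowers the other counts. A share of 1 in 100 argues against chance in how these arrays fall into groups, but the 0 is no measure of the margin. Chance between cultures is not covered if the arrays of a group are repeats of 1 culture. For the comparisons of 3 against 3 arrays 1 of 10 splits, the real one, gave as many genes, and these splits are too few for a share under 0.05. The other splits mix the arrays of both groups, which also lowers their counts. The real and highest other counts were 4299 and 1 for lactic acidosis, 6436 and 0 for hypoxia and 5674 and 0 for the combined arrays, each against control. They were 6676 and 0 for combined against hypoxia and 5389 and 0 against lactic acidosis.

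Called lists with a negative median interaction were HIF targets in glycolysis (-1.11) and elsewhere (-2.245), the amino acid response (-0.293) and p53 targets (-0.567). Among called lists, positive medians were found for aminoacyl-tRNA synthetases (0.333), chaperones of the endoplasmic reticulum (0.333), cholesterol synthesis (0.361) and oxidative phosphorylation (0.397). All of these fell below 0 after spike-in scaling. Positive medians were also found for DNA replication (1.337), fatty acid synthesis (0.742), the tricarboxylic acid cycle (0.627), ribosome biogenesis (0.911), heat shock proteins (0.717) and histones (1.367). With an estimated correlation 4 of the 14 called lists passed, namely both lists of HIF targets, DNA replication and ribosome biogenesis. The largest positive interactions of single genes were those of *CCN2* (3.403), *PDZK1* (3.238), *MCM10* (3.214), *H2BC11* (3.204), *CTPS1* (3.2), *MAOB* (2.871), *GPATCH2* (2.782) and *SRM* (2.741). That of *CCN2* rests on values near or below the lower quartile of the arrays in every group but the combined one. The largest negative ones were those of *TMEM45A* (-6.452), *LOXL2* (-6.189), *NDRG1* (-5.947), *PPFIA4* (-5.761), *SPAG4* (-5.198), *TGFBI* (-5.019), *LOX* (-5.00) and *SAMD4A* (-4.946). Among genes fixed in advance, negative interactions were those of *EPAS1* (-2.639), *VEGFA* (-2.976), *ADM* (-2.214), *PDK1* (-2.162), *LDHA* (-0.916), *SLC2A1* (-1.107), *EGLN3* (-3.324), *BNIP3* (-3.376), *ATF4* (-0.816), *ASNS* (-0.695), *TRIB3* (-1.608), *TXNIP* (-2.298), *MYC* (-1.382) and *CDKN1A* (-0.655). Positive ones were those of *HIF1A* (0.778), *ATF3* (1.199), *DDIT3* (0.813), *HSPA5* (1.375), *XBP1* (0.259), *ESR1* (0.83) and *PGR* (1.315). The *XBP1* interaction was not past the threshold without control replicate 1, lactic acidosis replicate 1 or combined replicate 1 (adjusted p = 0.0548, 0.0508 and 0.0513) or after renewed quantile normalisation (0.0738).

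Genes raised by hypoxia were less raised in the combined arrays. Of 3050 such genes 1315 were higher and 624 lower than control there. Against the hypoxia arrays 2041 of them were lower, 183 higher and 826 not past the threshold. Scaling of the arrays against a lower mRNA content, which would shift all genes of an array alike and upward, is argued against as the whole cause. Against hypoxia the median of HIF targets outside glycolysis less that of DNA replication genes was -2.895 (-1.896 and 0.999, quartiles -2.601 to -1.058 and 0.636 to 1.435). That the combined cells in fact stood in ambient oxygen is not decided. Of 37 HIF targets outside glycolysis 30 differed from lactic acidosis, but 12 were higher and 18 lower, and without knowledge of separate cultures such differences do not tell oxygen from handling. An exchange of the labels of the hypoxia and combined groups is not excluded. The correlation of both acid effects across genes (-0.336, or 0.153 over 6047 genes within 0.2 of control in hypoxia) does not decide it. With exchanged labels, 1% oxygen at neutral pH would have raised 24 of 37 HIF targets outside glycolysis and lowered 6 (median 0.394). In glycolysis it would have raised 11 of 23 and lowered 2 (median 0.118). The arrays labelled hypoxia had all 37 and 22 of 23 raised (medians 2.51 and 1.122). For targets of HIF this argues against an exchange, but does not exclude it, as 24 of 37 rose. Exchanged labels would not remove the interaction, as 5713 genes then passed, but would turn its direction, with medians of 1.479 for HIF targets outside glycolysis and -0.829 for DNA replication genes. The interaction that the design names stays open as a hypothesis, and its direction depends on the labels.

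The poly-A controls, which no comparison of genes used, were brighter than in control by 0.856 in the combined and 0.359 in the hypoxia arrays. Hybridisation, staining or scanning is argued against by the hybridisation controls, which were 0.14 higher in the combined arrays. More spike-in per amount of RNA in these samples and a lower mRNA content of the cells' RNA cannot be told apart, because the 4 spike-ins rose by amounts within a range of 0.225 under either and the spike-in amounts are not given in the sources used here.

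Among genes changed at least 2-fold with several probe sets, 34 of 239 had probe sets called in opposite directions in combined against control, and 8 of 477 in hypoxia against control (Fisher's exact p = 8.72e-11). Fisher's test treats genes as independent replicates, which they are not. Both contrasts also share the control arrays and some of the genes, such as *CTTN* and *USP46*. The Fisher p values of this paragraph therefore do not measure the spread between arrays or cultures. Probe sets near the background and cross-hybridising probe sets are argued against. The ratio of these shares was 16.2 without the dimmest probe sets and 6.14 without probe sets ending in _x_at or _s_at. The brightest called probe set was lower than control in 28 of the 34 genes and in 140 of the 205 without opposite probe sets (Fisher's exact p = 0.108), which leaves a link with brightness open. A scaling of the arrays against a lower mRNA content is not decided, as the ratio fell to 0.274 after spike-in scaling, but 11702 of 11815 called genes were then lower, which leaves few genes to differ in sign. With the dimmest probe sets left out, those of a gene lay over 1 log2 unit apart in 130 of 2802 genes in the combined arrays. The number was 99 in hypoxia and 28 in lactic acidosis, each against control. Between pairs of arrays of the same group it ran from 0 to 28 (median 0). No biological explanation was tested.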

How the results depend on the processing

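The scaling on poly-A controls was chosen after seeing the data. Of the named-gene values under the other alternatives, 16857 kept direction and side of the threshold, 169 fell short of it, 49 newly passed and 11 reversed. With that scaling 627 of 786 kept both, 37 fell short, 17 newly passed and 105 reversed. Of the list values under the other alternatives, 3257 kept both, 91 fell short and 42 newly passed. With that scaling 30 of the 74 called list medians changed sign, and camera was not run again. Of the other results 387 stayed and 29 moved, a count by over 1.5 times and a correlation by over the SD of its leave-one-out values. With every probe set tested, which tests more features, 6941 (lactic acidosis), 10677 (hypoxia) and 9450 (combined) probe sets passed against control, 11124 in combined against hypoxia, 8982 against lactic acidosis and 10364 in the interaction. After spike-in scaling 2393 genes passed in lactic acidosis, 11815 in the combined arrays and 11607 in combined against lactic acidosis, and the cause was not tested. With an estimated correlation 5 lists passed in hypoxia and 3 in the combined arrays against control, 5 against hypoxia, 3 against lactic acidosis and 4 in the interaction. After renewed quantile normalisation 7 lists passed in combined against control, and the cause was not tested.

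With the mean of a gene's probe sets, combined against control reversed for *ACACA* (0.177), *MDM2* (0.161), *RRP1B* (0.073) and *ESR1* (0.118), and combined against lactic acidosis for *IGF1R* (0.182), *MDM2* (0.067), *VEGFA* (1.124) and *ESR1* (0.144), because their probe sets disagree. Of the reversed values, those of *RRP1B* and of *MDM2* against lactic acidosis were not past the threshold (adjusted p = 0.166 and 0.265). Without probe sets ending in _x_at, *SPCS3* changed sign against control (0.157, adjusted p = 0.149) and against lactic acidosis (0.502, adjusted p = 0.000274). *GDF15* did so in the interaction (0.016, adjusted p = 0.899), each on another probe set. The correlation of the acid effects was -0.324 with the mean of probe sets, -0.372 without the dimmest genes and -0.342 after quantile normalisation, and that of the hypoxia effects -0.05 and -0.076 for the first 2 settings; the cause was not tested.

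Leaving out 1 array at a time gave 3687 to 4270 genes in lactic acidosis, 6002 to 6582 in hypoxia and 4795 to 5892 in the combined arrays against control. It gave 6196 to 6822 in combined against hypoxia, 4808 to 5355 against lactic acidosis and 5970 to 6277 in the interaction. The correlations ran from -0.345 to -0.327 and from -0.08 to -0.06. Called lists numbered 11 to 12, 12 to 14, 10 to 12, 12 to 13, 10 to 15 and 13 to 14 in the order of those contrasts. With the replicate number as a block 4172, 6385, 5567, 6654, 5315 and 6201 genes passed in that order. After subtraction of the group means, arrays of the same number correlated at only -0.2 to 0.135, and 5 of 12 matched best with their own number. This gives no sign that the numbers pair the arrays, though 3 arrays per group allow only a weak check. The fit with only the arrays compared was not run for the interaction, which needs all 12. Changes of 0.25 log2 units were recovered in 14% to 58% of simulated genes. With 200 genes changed in each simulation, far fewer than passed here, these shares understate the recovery in the real data.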

Other observations

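The tests of scaling for immediate early genes and of S phase for histones were chosen only after the result was seen. A pair of genes departed from the lists they stand in. *H4C8*, a histone H4 gene, was 1.93-fold lower in lactic acidosis, 4.35-fold higher in hypoxia and 4.01-fold lower in combined than in hypoxia arrays, while most other histone genes were higher there. *IDH2*, a mitochondrial isocitrate dehydrogenase, was 2.02-fold higher in hypoxia, where most genes of the tricarboxylic acid cycle fell.

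*AKR1B10*, an aldo-keto reductase, was 2.73-fold higher in lactic acidosis and 2.24-fold lower in hypoxia. *ABCC3*, an organic anion exporter, was 2.95-fold higher in lactic acidosis and 3.62-fold lower in combined than in lactic acidosis arrays. *GLA*, a lysosomal galactosidase, was 1.90-fold lower in lactic acidosis and 3.41-fold lower in hypoxia, with an interaction of 2.29 ± 0.065. The probe set for Alu repeats averaged 13.99 in control, 13.97 in lactic acidosis, 13.89 in hypoxia and 13.54 in the combined arrays.

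A first hypothesis was that immediate early genes are higher in the combined arrays through array scaling alone. After spike-in scaling their median stayed above control, at 0.413, which argues against it. A second was that histone genes are higher because more cells were in S phase. The median of DNA replication genes against control was -0.028, which argues against it as the whole cause.

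Another hypothesis was that *CCN1* and *CCN2*, known targets of YAP and TEAD, are higher in the combined arrays because these factors were active. Of 18 other targets 4 rose and 3 fell there (median 0.059). The p of camera, the list test of limma, was 0.507, which leaves this open. A further one was that *CYP1A1* is higher because the aryl hydrocarbon receptor was active. Of 5 other targets 3 rose and none fell in the combined arrays (median 0.189), with a camera p of 0.0365, or 0.144 adjusted over 12 tests. In hypoxia, where *CYP1A1* was highest, 2 rose and 1 fell (median 0.09), with a camera p of 0.304, or 0.521 adjusted over 12 tests, which leaves it open as well.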
